A study of Arabidopsis thaliana with 12 samples.

How the data were processed

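RNA was sequenced from whole Arabidopsis seedlings of the Columbia wild type grown at 22 °C under a photoperiod of 10 h in white light of 100 µmol m-2 s-1 with a red to far-red ratio of 1.1. Seedlings 3 days old were moved to shade or white light at 20 or 28 °C for 10 h on day 4. Per the labels, 3 µg of RNA and 12 PCR cycles were used for polyA libraries that were sequenced as read pairs. The kit was not stated to keep the strand.

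The columns of the deposited table were headed ambient or heat where the sample titles gave a temperature, and ambient was taken as 20 °C and heat as 28 °C. The deposited values are in another unit than reads: the authors gave log2 values on the voom scale, log2 CPM with 0.5 read added, with no further scaling factor. TopHat2 2.1.1, SAMtools 1.3, limma and R 4.0.2 were named for the upstream steps, with TAIR10 as genome build; their roles and the read counter were not given in the sources used here. Whole reads were recovered from 100% of the values within 0.001 read. The 12 library totals lay between 3500325 and 4481869 reads, so 1 CPM stood for 3.50 to 4.48 reads. Reads were not marked as unique molecules, and floors cover counting error only.

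Genes were tested when at least 3 of the 12 libraries had a log2 value of at least 0. This kept 21316 of 33602 genes; of the other 12286, which held 0.0520% of reads, 8802 had no read. The 4 group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trended prior), with Benjamini-Hochberg adjustment over tested genes and a threshold of 0.05. The contrasts were the pairs of groups that differ in 1 factor, shade with warmth against white light at 20 °C, the interaction, shade alone against warmth alone, and the average effects. The 24 gene lists, written from textbook knowledge, were tested with camera at a preset correlation of 0.01, and with an estimated correlation (statmod 1.5.0) and fry beside it, adjusted over lists within a comparison. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

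Groups, tests, lists and the rule for named genes were fixed before the data were examined. The rule took the 6 largest rises and falls per comparison among genes past the threshold with a mean log2 value of at least 1 and, for pairs of groups, no overlap between them, the 4 list members with the smallest adjusted p, and a set of key light, growth, heat and clock genes. Symbols came from an annotation of a later release than the build named by the authors, so no coordinates are given; 32835 identifiers were matched and 767 were not, 181 of them tested. Reads of 183 tested genes in 88 sets were identical, so overlapping or duplicated genes cannot be separated.

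In tests on simulated data with 3 libraries per group, 30% of genes changed 1.5-fold, 80% of those changed 2-fold and 96% of those changed 3-fold were recovered for warmth in white light, and 52% of 2-fold changes for the interaction. Libraries with the same replicate number were not more alike than others (residual correlations of -0.03 to 0.041 over 18 pairs), so replicates were treated as unpaired. Alternatives covered the prior variance, the filter, scaling, the added constant, weights, a replicate block and each library left out. Trimmed mean scaling, leaving out ribosomal and organelle genes, leaving out the genes of the photosynthesis list, and leaving out the libraries with most 18S reads were added after seeing the data.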

Results

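Transcript levels were measured by RNA sequencing in whole seedlings of Arabidopsis thaliana, accession Columbia, that were exposed to shade, to warmth, to both or to neither. The 4 groups combined white light or shade with a temperature of 20 or 28 °C, and each had 3 biological replicates. The exposure lasted the 10 h light period of day 4, and seedlings were collected at its end. The 12 libraries held between 3500325 and 4481869 reads assigned to genes, and 21316 of 33602 listed genes were tested. The first principal component of the tested genes took 21.0% of the variance and placed the white light 20 °C libraries between -62.2 and -57.2, apart from every other library. The second took 13.1% and placed the white light 28 °C libraries between 36.9 and 49.0 and the shade libraries between -44.6 and -12.4. 18S ribosomal RNA took 1.60 ± 0.632% of the reads in the libraries at 28 °C and 0.866 ± 0.416% at 20 °C (SD, n = 6 each; 2-sided exact permutation p = 0.0455).

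**Figure D1:**
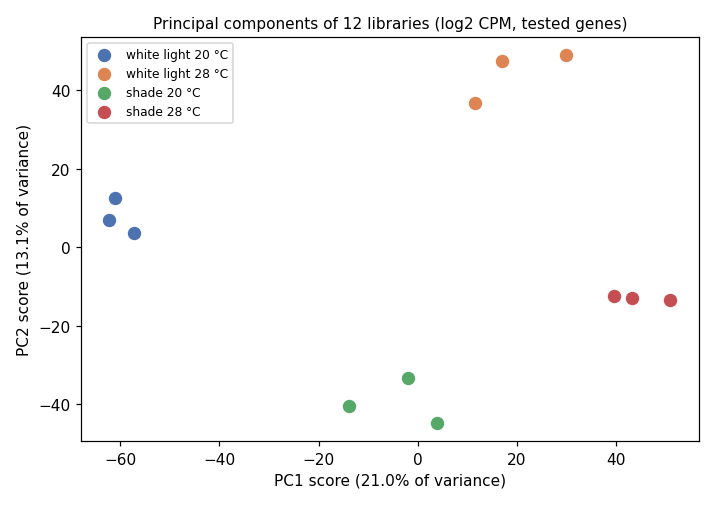
Scores of the 12 libraries on the first and second principal components of the log2 CPM values of tested genes, one point per library, coloured by group. The white light 20 °C libraries lie at the low end of the first component, and the white light 28 °C and shade libraries lie on opposite sides of the second.

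The first comparison asked what warmth alone changed in white light. Heat shock genes rose and cold-responsive, photosynthesis and flavonoid genes fell. HSP18.2 (AT5G59720), a small heat shock protein, rose by 6.46 ± 0.29 on the log2 scale (SE, n = 3 per group; limma adjusted p = 2.2e-14). COR15A (AT2G42540), a chloroplast protein of cold-treated plants, had a log2 change of -4.95 ± 0.68 (limma adjusted p = 9.7e-06). SEs of log2 changes are limma values with a spread estimated over all 4 groups. In white light at 28 °C, COR15A was at 1.999, -0.705 and -3.143, the last without a read. The size of its changes against that group is therefore uncertain. In total 2310 genes rose and 1023 fell, and 719 of these 3333 genes changed at least 2-fold. The count was 1950 with a constant prior variance and 1803 without the libraries with most 18S reads.

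Of 23 tested members of the heat list, 16 rose and 0 fell, or 17 and 0 adjusted over the list alone, with a median log2 change of 1.43. HSP70 (AT3G12580) rose by 1.82 ± 0.18, HSP90.1 (AT5G52640) by 1.97 ± 0.18 and HSP101 (AT1G74310), a disaggregating chaperone, by 0.93 ± 0.22. HSP22.0 (AT4G10250) had no read in the white light 20 °C libraries and was at least 47.1-fold higher at 28 °C against a floor of 3 reads over the group. Among the genes with the largest rises were also GolS1 (AT2G47180), which makes galactinol, at 4.55 ± 0.33, and AT1G72660 at 4.28 ± 0.42. The cold and abscisic acid list had 0 members rise and 7 of 11 fall, or 7 adjusted over the list alone, with a median of -1.58. RD29A (AT5G52310) changed by -2.98 ± 0.14, KIN1 (AT5G15960) by -1.90 ± 0.14 and KIN2 (AT5G15970) by -1.58 ± 0.11. KIN1 and KIN2 are close paralogs whose reads may be split between them, so their separate levels are uncertain. The chloroplast beta-amylase CT-BMY (AT4G17090) changed by -3.03 ± 0.17 and the expansin EXPA17 (AT4G01630) by -3.44 ± 0.72.

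Photosynthesis genes fell together: 23 of 24 members of that list were lower and 0 higher, also 23 adjusted over the list alone, with a median log2 change of -0.79. The light-harvesting genes LHCB2.1 (AT2G05100) and LHCB1.1 (AT1G29920) changed by -1.37 ± 0.10 and -1.36 ± 0.15. RBCS1A (AT1G67090), a Rubisco small subunit gene, changed by -0.63 ± 0.18 (limma adjusted p = 0.0147), a call that was lost without replicate 3 of white light at 28 °C (-0.46, limma adjusted p = 0.0596), after quantile normalization (-0.24), with a constant or robust prior variance, without the filter on low values and without the libraries with most 18S reads. LHCB1 and RBCS genes have near-identical copies, so the levels of single copies are uncertain. The photosynthesis list took 10.2 ± 0.38% of all reads in white light at 20 °C and 6.17 ± 1.06% at 28 °C (SD, n = 3). In the flavonoid list 10 of 18 members fell and 0 rose, or 13 and 0 adjusted over the list alone, with a median of -1.33. Chalcone synthase, CHS (AT5G13930), changed by -0.76 ± 0.13 and DFR (AT5G42800) by -1.99 ± 0.48. The list also held ELIP1 (AT3G22840), at -1.32 ± 0.19, and ELIP2, which are early light-induced protein genes and not flavonoid genes. Of 17 clock genes 6 fell and 1 rose, the same counts as adjusted over the list alone. PRR5 (AT5G24470) changed by -1.59 ± 0.13, ELF4 (AT2G40080) by -1.12 ± 0.11 and FKF1 (AT1G68050) by -0.81 ± 0.12.

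In white light at 28 °C, members of the cell wall, brassinosteroid and low-energy lists rose, but these lists passed camera only at the preset correlation. Of 20 expansin and xyloglucan-modifying genes 9 rose and 0 fell, or 13 and 0 adjusted over the list alone, with a median of 0.47 (adjusted p = 0.0527 with an estimated correlation). EXPA8 (AT2G40610) rose by 1.81 ± 0.12 and EXPA3 (AT2G37640) by 1.23 ± 0.14. In the brassinosteroid list 4 of 11 members rose and 1 fell, or 5 and 1 adjusted over the list alone, among them CPD (AT5G05690) at 0.68 ± 0.12 and BR6OX2 (AT3G30180) at 0.92 ± 0.17 (adjusted p = 0.0902 with an estimated correlation). In the low-energy list, genes induced by carbon starvation, 12 of 15 rose and 0 fell, or 13 and 0 adjusted over the list alone; SEN1 (AT4G35770) rose by 1.54 ± 0.15 and BCAT2 (AT1G10070) by 1.44 ± 0.21 (adjusted p = 0.131 with an estimated correlation). The auxin response list did not pass camera (adjusted p = 0.58), although 4 of 26 members rose, IAA29 (AT4G32280) by 1.53 ± 0.30 and GH3.3 (AT2G23170) by 1.01 ± 0.18. The IAA29 call was lost with voom weights (limma adjusted p = 0.0676). The shade marker list did not pass either (adjusted p = 0.255); XTH15 (AT4G14130) rose by 1.83 ± 0.19, while HFR1 (AT1G02340) at 0.24 ± 0.23 and PIL1 (AT2G46970) at 0.98 ± 0.48 did not pass. Of 21 light signalling genes, which include photoreceptors and PIFs, 2 rose and 3 fell. PHYA (AT1G09570) rose by 0.97 ± 0.12 and PHYB (AT2G18790) changed by -0.44 ± 0.12, while PIF4 (AT2G43010) at 0.04 ± 0.14 did not pass. PIF3 (AT1G09530) was at 5.491, 5.645 and 5.436 at 20 °C and at 5.894, 6.372 and 6.697 at 28 °C, without overlap. Without replicate 2 of white light at 28 °C, PHYB was at -0.36 and no longer passed, and PIL1 was at 1.51 and passed (limma adjusted p = 0.037). The auxin biosynthesis gene YUC8 (AT4G28720) at 0.46 ± 0.20 did not pass. The immune receptor gene SNC1 (AT4G16890) changed by -1.08 ± 0.13. Chlorophyll biosynthesis, with 1 rise and 2 falls among 10 members, and jasmonate, with 0 and 1 among 10, passed camera in the falling direction (adjusted p = 0.0398 for both), but not with an estimated correlation (adjusted p = 0.117 and 0.131). The lists of light signalling, B-box factors, growth bHLH factors, gibberellin, ethylene biosynthesis, salicylic acid defence, glucosinolates, cell cycle, stomatal lineage, root markers and seed storage did not pass camera in this comparison (adjusted p = 0.255, 0.144, 0.888, 0.888, 0.255, 0.328, 0.668, 0.58, 0.564, 0.82 and 0.564), nor did auxin biosynthesis (adjusted p = 0.58). With fry, which tests a list without comparing it to other genes, some lists that did not pass camera rose. These were auxin response, auxin biosynthesis, shade markers and ethylene biosynthesis (fry adjusted p = 0.00177, 0.00453, 0.00361 and 0.0435). Their median log2 changes were 0.19, 0.41, 0.24 and 0.42, where that of all tested genes was 0.16. Because fry makes no comparison with other genes, it cannot separate a rise of these lists from that general shift. Chlorophyll biosynthesis and jasmonate did not pass fry (adjusted p = 0.0795 and 0.115). Over all comparisons 95 list tests passed camera, where random regroupings of the 12 libraries gave a median of 68.

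The median of all tested genes lay 0.16 log2 units higher at 28 °C in white light, and the split between rises and falls moved with the scaling. As deposited, 69.3% of the genes called had risen; after subtraction of each library's median the share was 39.8%, after quantile normalization 46.1%, with trimmed mean scaling 43.2% and without the genes of the photosynthesis list 58%. None of the genes named for this comparison changed sign in a way that passed the test under these scalings.

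**Figure D2:**
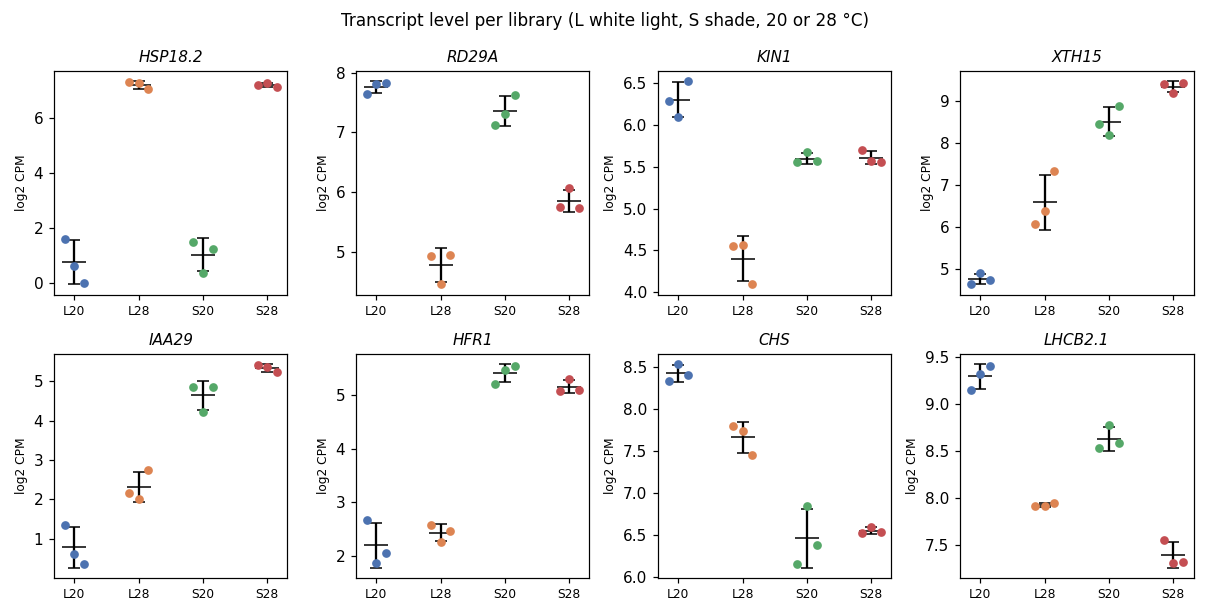
Level of 8 genes in each library as log2 CPM, with the mean and SD of 3 libraries per group; vertical axes differ between panels and do not start at 0. HSP18.2 was high in both 28 °C groups, HFR1 in both shade groups, and KIN1 was lowest in white light at 28 °C.

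The second comparison asked what shade alone changed at 20 °C. Shade markers and auxin-responsive genes rose, and flavonoid genes fell. XTH15, a xyloglucan-modifying enzyme, rose by 3.75 ± 0.19 (SE, n = 3 per group; limma adjusted p = 3.35e-13), and PIL1, a bHLH factor, by 3.98 ± 0.48 (limma adjusted p = 1.1e-06). In total 1158 genes rose and 566 fell, of which 458 changed at least 2-fold.

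Of 15 shade markers 13 rose and 0 fell, also 13 adjusted over the list alone, with a median log2 change of 1.17; HFR1 rose by 3.21 ± 0.23 and the homeobox gene HB-2 (AT4G16780) by 2.26 ± 0.24. Of 26 auxin-responsive genes 12 rose and 0 fell, or 17 and 0 adjusted over the list alone, with a median of 1.52. IAA29 rose by 3.86 ± 0.30, IAA19 (AT3G15540) by 1.92 ± 0.18 and GH3.3 by 2.03 ± 0.18. SAUR22 (AT5G18050) rose by 4.31 ± 0.62, but belongs to a cluster of near-identical copies and its own level is uncertain. The auxin biosynthesis list did not pass camera (adjusted p = 0.633), with 1 of 9 members risen, YUC8 at 1.57 ± 0.20. By fry that list rose (adjusted p = 0.0066), with a median log2 change of 0.094 where that of all tested genes was 0.055. Of 20 cell wall loosening genes 13 rose and 1 fell, the same adjusted over the list alone, with EXPA8 at 2.14 ± 0.12, XTH4 (AT2G06850) at 1.49 ± 0.11 and EXPA3 at 1.48 ± 0.14. In the brassinosteroid list 4 of 11 rose, or 6 adjusted over the list alone, among them CPD at 0.96 ± 0.12 and the receptor gene BRI1 (AT4G39400) at 0.60 ± 0.09. Low-energy genes rose in 13 of 15 cases, or 14 adjusted over the list alone, with ASN1 (AT3G47340) at 3.07 ± 0.31, BCAT2 at 2.54 ± 0.21 and SEN1 at 1.73 ± 0.15. The largest rises also held RTFL21 (AT1G67265) at 5.54 ± 0.71 and AT5G02540 at 4.52 ± 0.27. The DELLA gene GAI (AT1G14920) rose by 1.19 ± 0.13, while PIF4 at 0.08 ± 0.14 and PIF7 (AT5G61270) at -0.26 ± 0.25 did not pass.

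In the flavonoid list 12 of 18 members fell and 0 rose in shade at 20 °C, or 15 and 0 adjusted over the list alone, with a median log2 change of -2.02. The late anthocyanin genes DFR, LDOX (AT4G22880), UF3GT (AT5G54060) and GSTF12 (AT5G17220) changed by -4.08 ± 0.48, -3.97 ± 0.76, -4.22 ± 0.60 and -3.85 ± 0.50. In shade LDOX was at -1.574, 2.013 and 0.664 and UF3GT at -0.837, 2.093 and -0.714, so the sizes of their changes are uncertain. CHS changed by -1.97 ± 0.13, FLS1 (AT5G08640) by -2.54 ± 0.27 and F3H (AT3G51240) by -2.07 ± 0.20; F3H held the same reads as an overlapping gene and is uncertain. Of 24 photosynthesis genes 17 fell and 0 rose, or 23 and 0 adjusted over the list alone (adjusted p = 0.0698 with an estimated correlation), with LHCB3 (AT5G54270) at -0.93 ± 0.13 and PSAE1 (AT4G28750) at -0.92 ± 0.12. In the chlorophyll biosynthesis list 2 of 10 fell. The cold list (2 of 11 fell), the jasmonate list (2 of 10) and the stomatal lineage list (0 of 10) passed camera in the falling direction but not with an estimated correlation (adjusted p = 0.152, 0.121 and 0.136). The heat list did not pass (adjusted p = 0.0648), and HSP70 changed by -0.86 ± 0.18, a call lost with a constant prior variance or without the filter on low values. Without replicate 3 of shade at 20 °C the count of genes called fell from 1724 to 1113, and with a constant prior variance to 919, with LDOX among the calls lost. The share that had risen was 67.2% as deposited, 52.9% after quantile normalization and 55.3% with trimmed mean scaling.

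The third comparison set shade and warmth together against white light at 20 °C. It gave 3173 rises and 1582 falls, with 1385 genes changed at least 2-fold, and joined the heat shock rise with the shade marker, auxin and cell wall rises. HSP18.2 rose by 6.46 ± 0.29 and XTH15 by 4.58 ± 0.19 (SE, n = 3 per group; limma adjusted p = 9.6e-15 and 2.2e-15).

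Of 26 auxin-responsive genes 17 rose, or 19 adjusted over the list alone, IAA29 by 4.56 ± 0.30 and IAA19 by 2.39 ± 0.18. Shade markers rose in 12 of 15 cases, or 14 adjusted over the list alone, cell wall loosening genes in 14 of 20, or 15, while 1 fell, with EXPA8 at 2.80 ± 0.12, and brassinosteroid genes in 7 of 11, with CPD at 1.29 ± 0.12. Heat genes rose in 14 of 23 cases, HSP70 by 0.87 ± 0.18, and low-energy genes in 14 of 15, ASN1 by 3.99 ± 0.31 and MCCA (AT1G03090) by 1.97 ± 0.16. BEE1 (AT1G18400), a bHLH factor, rose by 1.71 ± 0.27. All 24 photosynthesis genes fell, LHCB1.1 by 2.60 ± 0.15 and LHCB2.1 by 1.91 ± 0.10 on the log2 scale, in libraries where the list took 4.90 ± 0.98% of the reads (SD, n = 3). Of 18 members of the flavonoid list 16 fell, with LDOX at -5.27 ± 0.76 and DFR at -5.01 ± 0.48. In shade at 28 °C LDOX was at -0.489, 0.689 and -2.998, the last without a read, and DFR at -0.489, -0.69 and 0.462. The sizes of both changes are therefore uncertain. Of 10 chlorophyll biosynthesis genes 7 fell, with CHLH (AT5G13630) at -1.05 ± 0.10, PORC (AT1G03630) at -0.74 ± 0.12 and CAO (AT1G44446) at -0.92 ± 0.14. Clock genes fell in 7 of 17 cases and rose in 1, PRR5 at -1.55 ± 0.13 and ELF4 at -1.37 ± 0.11. RD29A changed by -1.91 ± 0.14 and PIF7 by -0.91 ± 0.25, a call lost without replicate 1 of white light at 20 °C (-0.80) or replicate 3 of shade at 28 °C (-0.69), and PHYA rose by 1.46 ± 0.12. SPCH (AT5G53210), which starts the stomatal lineage, changed by -2.37 ± 0.51. The light signalling, cold, jasmonate and stomatal lineage lists passed camera but not with an estimated correlation (adjusted p = 0.217, 0.0844, 0.108 and 0.0537). The share that had risen was 66.7% as deposited, 44.5% after median subtraction, 47.5% after quantile normalization and 48.2% with trimmed mean scaling.

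**Figure D3:**
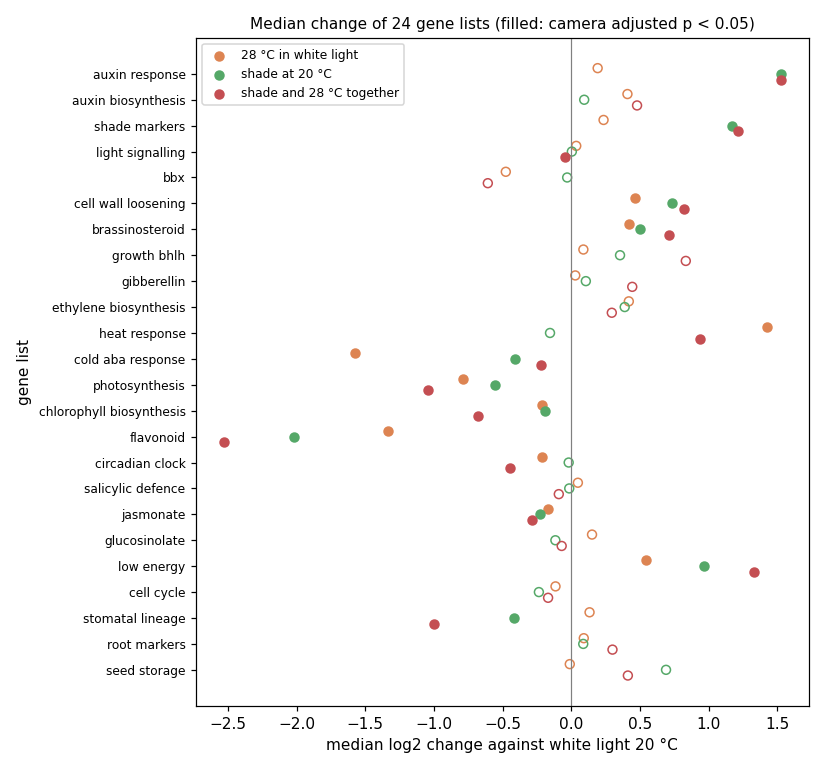
Median log2 change of 24 gene lists against white light at 20 °C for warmth, shade and both together; filled points passed camera and open points did not. The heat list lay at 1.43 with warmth in white light and the flavonoid list at -2.02 with shade.

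Shade at 28 °C was set against white light at 28 °C. Auxin-responsive genes and shade markers rose, in 16 of 26 and 10 of 15 cases (20 and 13 adjusted over the list alone), and cold-responsive genes were higher in 6 of 11 cases. IAA29 rose by 3.03 ± 0.30, IAA19 by 2.22 ± 0.18, HB-2 by 2.66 ± 0.24, XTH15 by 2.76 ± 0.19 and HFR1 by 2.73 ± 0.23 (SE, n = 3 per group). In total 572 genes rose and 406 fell by limma, and these 978 genes became 357 with a constant prior variance, 612 without the filter on low values and 600 without the libraries with most 18S reads. COR15A rose by 3.39 ± 0.68, AIR1 (AT4G12550) by 3.11 ± 0.44, RTFL21 by 3.40 ± 0.71 and SAUR21 (AT5G18030), another of the near-identical SAUR copies, by 3.23 ± 0.51. DFR changed by -3.02 ± 0.48, CHS by -1.11 ± 0.13, MYB75 (AT1G56650), an anthocyanin regulator, by -3.17 ± 0.65, and the glucosinolate genes CYP83A1 (AT4G13770) and IPMI2 (AT2G43100) by -3.77 ± 0.67 and -3.34 ± 0.78. In shade at 28 °C MYB75 was at -2.811, -0.204 and 0.462, the first without a read, and DFR at -0.489, -0.69 and 0.462. The sizes of their changes are therefore uncertain. The IPMI2 call was lost without replicate 2 of white light at 28 °C (-3.16) or replicate 3 of shade at 28 °C (-2.19), and those of COR15A, RTFL21, MYB75 and IPMI2 with a constant prior variance or without the filter on low values, that of COR15A also with a robust prior variance and that of MYB75 also with voom weights. PHYB rose by 0.55 ± 0.12 and HSP70 changed by -0.95 ± 0.18, both calls lost with a constant prior variance. The growth bHLH, heat, photosynthesis and root marker lists passed camera but not with an estimated correlation (adjusted p = 0.0561, 0.157, 0.1 and 0.217). In the glucosinolate list 3 of 9 members fell and 0 rose, or 4 and 1 adjusted over the list alone. That list passed neither camera (adjusted p = 0.178) nor fry (adjusted p = 0.0595). Of the genes that rose with shade at 20 °C, 403 also rose with shade at 28 °C, where independent lists would share 31.1.

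Warmth under shade was set against shade at 20 °C. Heat genes rose in 14 of 23 cases (16 adjusted over the list alone) and photosynthesis genes fell in 18 of 24 (24). HSP18.2 rose by 6.18 ± 0.29, GolS1 by 3.55 ± 0.33, HSP70 by 1.73 ± 0.18 and XTH15 by 0.83 ± 0.19 (SE, n = 3 per group), and PP2-A5 (AT1G65390) changed by -2.62 ± 0.38. The XTH15 call was lost without replicate 1 (0.81) or 2 (0.68) of shade at 20 °C or replicate 3 of shade at 28 °C (0.79), with a constant or robust prior variance and without the filter on low values. IAA29 at 0.69 ± 0.30 did not pass. In total 467 genes rose and 425 fell by limma, and 5 of 17 clock genes and 3 of 10 chlorophyll genes fell. The auxin response, light signalling, flavonoid, low-energy and root marker lists passed camera but not with an estimated correlation (adjusted p = 0.0969, 0.117, 0.288, 0.288 and 0.338). The count of 892 genes fell to 402 without replicate 2 of shade at 20 °C, to 513 without its replicate 1, and to 457 and 533 without replicates 2 and 3 of shade at 28 °C; it was 184 with a constant prior variance, 370 without the filter on low values and 566 without the libraries with most 18S reads. The share that had risen was 52.4% as deposited, 25.1% after median subtraction, 39.4% after quantile normalization and 33.1% with trimmed mean scaling.

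The interaction asked which genes responded to warmth differently in shade and in white light. Cold-responsive genes fell with warmth in white light and changed less under shade, and the cell wall genes EXPA8, EXPA3 and XTH4 had lower values of the warmth effect under shade: EXPA8 rose by 1.81 ± 0.12 in white light and by 0.65 ± 0.12 under shade. KIN1 changed by -1.90 ± 0.14 with warmth in white light and by 0.01 ± 0.14 under shade, an interaction of 1.91 ± 0.20 (SE, n = 3 per group; limma adjusted p = 5.2e-06). In total 27 genes had a positive and 68 a negative interaction. KIN2 had an interaction of 1.63 ± 0.16, RD29A of 1.48 ± 0.19 and CT-BMY of 1.53 ± 0.24. In the cold list 3 of 11 members passed, or 7 adjusted over the list alone, with a median of 1.48 (camera adjusted p = 8.8e-18, and 0.00345 with an estimated correlation). EXPA8, EXPA3, XTH4 and XTH9 (AT4G03210) had negative interactions of -1.16 ± 0.16, -0.92 ± 0.20, -0.70 ± 0.15 and -0.70 ± 0.15; the last 3 of these calls were lost in 13, 12 and 5 of 26 alternative settings. XTH9 was at 0.23 ± 0.10 with warmth in white light and changed by -0.47 ± 0.10 under shade. The interaction was also negative for PORB (AT4G27440), a chlorophyll biosynthesis enzyme, at -1.34 ± 0.16. The cell wall, flavonoid, chlorophyll, photosynthesis, low-energy and root marker lists passed camera but not with an estimated correlation (adjusted p = 0.106, 0.106, 0.106, 0.791, 0.471 and 0.471). The count of 95 was 6 with a constant prior variance, of which 2, KIN1 and KIN2, were among the 95; it was 40 without the filter on low values, 51 without the libraries with most 18S reads, 59 without replicate 3 of shade at 20 °C, 61 without replicate 3 of shade at 28 °C and 155 without replicate 1 of white light at 28 °C, and random regroupings gave 95 or more in 5 of 100 cases, the real one included. The share with a positive interaction was 28.4% as deposited, 39.4% after median subtraction, 47.4% after quantile normalization and 44.1% with trimmed mean scaling.

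Shade alone was also set directly against warmth alone. Shade markers, auxin-responsive genes and cold-responsive genes were higher in shade at 20 °C, and heat genes were higher in white light at 28 °C. HFR1 was higher in shade by 2.98 ± 0.23, PIL1 by 2.99 ± 0.48, HB-2 by 2.65 ± 0.24, IAA19 by 1.75 ± 0.18, IAA29 by 2.34 ± 0.30 and COR15A by 4.52 ± 0.68 (SE, n = 3 per group). HSP18.2 differed by -6.19 ± 0.29, GolS1 by -3.62 ± 0.33, HSP70 by -2.68 ± 0.18, UGT73C1 (AT2G36750) by -3.62 ± 0.69 and CHS by -1.21 ± 0.13. AIR1 was higher in shade by 3.29 ± 0.44 and PHYB by 0.68 ± 0.12. In total 737 genes were higher in shade and 936 higher in warmth by limma, and these 1673 genes became 802 with a constant prior variance and 1057 without the filter on low values. Of 23 heat genes 18 were lower in shade, of 15 shade markers 9 were higher, and of 17 clock genes 7 were higher. The cell wall, photosynthesis, flavonoid and low-energy lists passed camera but not with an estimated correlation (adjusted p = 0.309, 0.389, 0.0771 and 0.205). The share higher in shade was 44.1% as deposited, 69.3% after median subtraction, 55.9% after quantile normalization and 62.6% with trimmed mean scaling.

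The series asked how far responses to shade and warmth converge. Averaged over the other factor, shade raised 1468 genes and lowered 997, and warmth raised 2796 and lowered 1267. The shade count of 2465 fell to 1466 with a constant prior variance, and the warmth count of 4063 to 2595 without the libraries with most 18S reads. The share that had risen with warmth was 68.8% as deposited, 37.6% after median subtraction, 46.8% after quantile normalization and 44.4% with trimmed mean scaling. Both rose for 543 genes, where independent lists would share 192.6, and both fell for 380, against 59.3. Shade raised and warmth lowered 53 genes, against 87.3, and 94 went the other way, against 130.8. Across 21316 genes, which are not independent replicates, the average shade and warmth effects had Pearson's r of 0.191 and Spearman's rho of 0.221. With no effect and genes drawn independently, simulation gave an r of 0.00026 ± 0.014 (SD). Random regroupings of the 12 libraries, which keep the correlation between genes, gave -0.279 to 0.29. Leaving out 1 library moved r between 0.107, without replicate 1 of white light at 28 °C, and 0.249, without replicate 2 of white light at 20 °C. Shade alone and warmth alone, which share the white light 20 °C libraries, had r of 0.533, while unchanged groups against those libraries gave 0.501. Their covariance was 0.201 against 0.0932 simulated, a difference of 0.108. Of the genes called in both, 611 rose in both, 302 fell in both and 12 went each opposite way; independent lists would share 125.5 and 27.2, and part of the excess may come from the shared libraries, of which a split would leave 1 on a side. Of 4120 genes called in either, 1288 differed between shade alone and warmth alone.

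**Figure D4:**
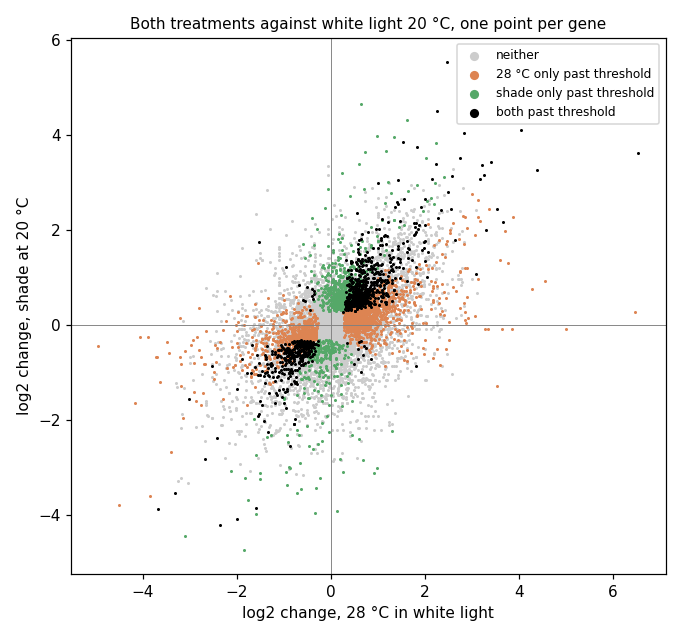
Log2 change with warmth in white light (horizontal) and with shade at 20 °C (vertical), one point per tested gene, coloured by which change passed the limma threshold. Of the genes past the threshold in both, 611 lie in the upper right and 302 in the lower left.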

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

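The low-oxygen and ethylene gene lists, the overlap of regroupings with the real contrasts, the fits without ribosomal and organelle genes and without the photosynthesis list, and the fit without the libraries with most 18S reads were chosen only after the interaction genes and library composition had been seen. By limma, 95 genes had a response to warmth that differed between shade and white light. Random regroupings of the 12 libraries into 4 groups of 3 gave as many in 5 of 100 cases, the real grouping included, so chance was not excluded. The highest other count, 378, was several times the real count and points to a structure of the samples. Of the 4 other regroupings with 95 or more, the one with 378 set 10 of 12 libraries on the sides of the real warmth contrast and the other 3 set 10 on the sides of the real shade contrast, so the shade and warmth effects may make up this structure; 9 and 8 of the 95 regroupings with fewer genes followed warmth or shade as closely.

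Each of the following was marked because the interaction test passed. Interactions on the log2 scale were 1.91 for KIN1, 1.63 for KIN2, 1.48 for RD29A, 1.53 for CT-BMY, 0.85 for CHS, 1.66 for CRK18, 1.55 for AT2G43620 and 1.51 for AT1G78450. Negative ones were -0.70 for XTH9, -1.16 for EXPA8, -0.92 for EXPA3, -0.70 for XTH4, -1.34 for PORB, -0.99 for SEN1, -0.81 for PHYA, -0.59 for ACO4, -3.76 for AT5G15120 and -3.00 for AT5G22580. The chloroplast pairs ATCG00930 and ATCG01200, each at -3.88, and ATCG00940 and ATCG01190, each at -3.47, held identical reads. LBD41 at -2.43, AT3G10040 at -2.74, AT4G27450 at -1.59, ETR2 at -2.06, EBP at -1.67, EBF1 at -1.06, EBF2 at -1.21 and EIN2 at -0.75 were chosen for naming after their values were seen. The median interaction was -0.49 for the cell wall list, 1.48 for the cold and abscisic acid list, 0.12 for photosynthesis, -0.15 for chlorophyll biosynthesis, 0.89 for flavonoids, -0.35 for low energy and 0.16 for root markers. Many of these calls were lost in other settings: of 26 alternatives, 12 of them with 1 library left out, ACO4 lost its call in 16, EXPA3 in 13, XTH4 in 12, AT1G78450 in 11, SEN1 and AT2G43620 in 10, AT5G22580 and CHS in 9, PHYA and CRK18 in 8, and XTH9 in 5. ATCG00930 and ATCG01200 lost it in 10 of 25, and ATCG00940 and ATCG01190 in 4 of 25. KIN1 and KIN2 lost it in 0 of 26, and the other named genes in 1 to 3. Of these lists, cold and abscisic acid passed with an estimated correlation (adjusted p = 0.00345).

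Low-oxygen genes had a weaker response to warmth under shade than in white light. The median interaction was -0.71 over 24 genes counted as not seen when the list was written. It was -1.32 over all 29, which include the genes that prompted the list. Of the 24, ETR2, AT4G27450 and AT3G27220 passed the interaction test themselves, and ETR2 counted as seen for the ethylene list. The 24 may therefore not be independent of the genes that prompted the list. Subtraction of library medians left -1.28 over the 29, which argues against library composition. Without replicate 3 of white light at 28 °C the median over the 29 was -0.70, against a bound of -0.66 and a bootstrap SD of 0.247. That library held 2.30% of 18S and 1.39% of chloroplast reads. Replicates 1 and 2 of its group held 1.12 and 0.839% of 18S, and 0.343 and 0.248% of chloroplast reads. A part played by replicate 3 cannot be told apart from a response of the group. A general low-oxygen response at 28 °C in white light (camera p = 4.04e-06 for the interaction over the 24 genes, 8.08e-06 adjusted over both lists, 0.0475 with an estimated correlation) and an ethylene response (p = 0.000249 over 12 genes not seen before, 0.000249 adjusted, 0.0388 with an estimated correlation) may both contribute. The estimated-correlation values lie close to the threshold, the rise of the 24 genes with warmth in white light had p = 0.0706 with an estimated correlation, and ETR2 belongs to both lists, so biological and technical explanations stay open.

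More genes rose than fell with warmth in white light, 69.3% of those called. Without ribosomal and organelle genes the share was 70.1%, a move within the spread of 1.94 over libraries left out, which argues against those reads as the source. Without the genes of the photosynthesis list, rescaled to the remaining reads, the share was 58% and the median change of all genes fell from 0.16 to 0.10, so fewer reads taken by these genes may account for part of the excess and not for the rest. After subtraction of library medians 39.8% had risen, but centring itself sets this balance, so that share does not bear on the source. Composition beyond the listed genes and a change in total RNA per seedling stay open.

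The average shade and warmth effects correlated across genes, with r of 0.191. The covariance of shade at 28 °C with warmth under shade leaves out the white light 20 °C libraries. It exceeded the simulated one by 0.0286 (SD 0.00297). The simulation drew each gene independently, so its SD leaves out variation that genes share. The excess thus cannot decide whether the white light 20 °C libraries standing apart are the whole source. The excess with those libraries was 0.108, and without them Pearson's r was 0.407 where unchanged groups gave 0.5003, so a large part played by them stays open. Without the libraries with most 18S reads r was 0.226, which argues against those libraries as the source. The libraries kept held 18S shares of 0.839 to 1.72% at 28 °C and 0.535 to 0.925% at 20 °C. A part played by ribosomal RNA that follows temperature therefore stays open. In 5 of 100 regroupings, the real one included, r was as large, with a highest other of 0.29, so chance was not excluded and a shared response is consistent with these values only as a hypothesis.

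Counts were 3333 genes for warmth in white light, 1724 for shade at 20 °C and 4755 for both together. They were 978 for shade at 28 °C, 892 for warmth under shade and 1673 for shade alone against warmth alone. For each, 1 of 10 splits, the real one, gave a count as large, and the highest other was 0. These 10 splits are too few for a share under 0.05. The 99 other random regroupings of the 12 libraries gave at most 666, 1840, 2250, 8, 61 and 135 genes in that order. For shade at 20 °C this highest count exceeded the real one. For the average shade effect 1 of 100 regroupings gave 2465 genes or more (highest other 1040), and for the average warmth effect 1 of 100 gave 4063 or more (highest other 342), so chance was excluded. For the 95 list calls over all comparisons 2 of 100 gave as many, with a highest other of 103. The other regroupings gave between 26 and 103 list calls, with a median of 68. The share for the total was under 0.05, but the highest other count exceeded the real one, so chance was not excluded for it. Nor was chance excluded for single list calls at the preset correlation.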

How the results depend on the processing

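Fits with trimmed mean scaling, without ribosomal and organelle genes, and without the photosynthesis list were chosen only after the data were seen. So was the fit without the library with most 18S reads in each of 3 groups. Of 160 named results under all alternatives, 4078 values stayed on their side of the threshold, 198 lost it, 3 gained it and 0 reversed; no list reversed. With a constant prior variance the counts were 1950 for warmth in white light, 919 for shade at 20 °C, 357 for shade at 28 °C, 184 for warmth under shade, 6 for the interaction, 802 for shade alone against warmth alone and 1466 for the average shade effect; the cause was not tested. With no filter on low values they were 612 for shade at 28 °C, 370 for warmth under shade, 40 for the interaction and 1057 for shade alone against warmth alone, with more genes tested. With the libraries highest in 18S left out they were 1803 for warmth in white light, 600 for shade at 28 °C, 566 for warmth under shade, 51 for the interaction and 2595 for the average warmth effect, with fewer libraries. The correlation across genes was 0.141 with no filter, 0.261 with a filter of log2 2, 0.207 after quantile normalization, 0.253 with 1 CPM added, 0.226 without the libraries highest in 18S and 0.221 by Spearman; the cause was not tested. With shared controls it was 0.533, which those libraries raise by construction: unchanged groups, simulated with independent genes, gave 0.501 (SD 0.00986). With an estimated correlation 55 of 95 list calls passed. Leaving out each library gave 2239 to 3413 genes for warmth in white light, 1113 to 1827 for shade at 20 °C, 3672 to 4825 for both, 656 to 985 for shade at 28 °C, 402 to 996 for warmth under shade, 59 to 155 for the interaction, 1130 to 1729 for shade alone against warmth alone, 1958 to 2486 for average shade, 3372 to 3839 for average warmth, 0.107 to 0.249 for the correlation and 89 to 98 for the lists. With a replicate block they were 3428, 1809, 4815, 1043, 974, 138, 1744, 2542 and 4178 in the same order, 0.191 for the correlation and 95 lists. Totals of 3500325 to 4481869 reads per library limit what can be said of weakly expressed genes.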

Other observations

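The low-oxygen and ethylene lists were chosen only after the interaction genes had been seen. Of 24 low-oxygen genes counted as not seen when the list was written, 9 rose and 0 fell with warmth in white light. Their median log2 change was 1.07 (camera p = 3.95e-05, but 0.0706 with an estimated correlation). Under shade 2 of them rose (median 0.30). Members not called with warmth in white light included ADH1, PDC2, SUS1 and SUS4 (limma adjusted p = 0.331, 0.481, 0.752 and 0.604). The 24 may not be independent of the genes that prompted the list. Of 12 ethylene response genes not seen before, 6 rose and 0 fell with warmth in white light, and 0 rose under shade. In white light camera gave p = 0.000206, and 0.0368 with an estimated correlation. Of the 6 that rose, HLS1, ERS2 and CTR1 were highest in replicate 3 of white light at 28 °C, and ERS1, ARGOS and ORS1 in replicate 2. No median without replicate 3 is given for the ethylene list, so a part played by that library stays open here too. Passing in white light and not under shade does not show a difference for single genes. By the interaction test 3 of the 24 (ETR2, AT4G27450 and AT3G27220) and 0 of the 12 passed, while 21 and 11 had interactions below 0. Over all 19 ethylene genes 7 passed, each of them set aside as seen. The 0 of the 12 thus follows in part from that split. With the genes that prompted the lists, 14 of 29 and 13 of 19 rose in white light, which is not independent evidence. AT5G15120 changed by 3.66 ± 0.48 with warmth in white light and by -0.10 ± 0.48 under shade, LBD41 by 2.26 ± 0.27 and -0.17 ± 0.27, and ETR2, an ethylene receptor gene, by 2.18 ± 0.22 and 0.11 ± 0.22 (SE, n = 3 per group). EBP changed by 1.86 ± 0.15 and 0.19 ± 0.15, and the F-box genes EBF1 and EBF2, which act in ethylene signalling, by 1.04 ± 0.12 and 1.18 ± 0.15 in white light; these genes were chosen after their values were seen.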
